A study of Drosophila melanogaster with 2 samples.

How the data were processed

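Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after egg laying. Per the labels, the flies carry a transgene that makes the protein CG13123 with green fluorescent protein (GFP) at its C terminus, and the precipitation used an antibody against GFP. Chromatin was sheared by sonication to a size range of 200 to 800, per the labels, which give no unit for it. The 2 samples form 1 group and are named in the labels as biological replicates 2 and 3. With 1 group there was no comparison of conditions, and every comparison below is between replicates or between peaks of the deposited lists.

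Per the labels and the deposited list of files, peaks were called against a control for each replicate and for the alignments of both replicates together. These relaxed lists hold peaks and background and serve as input for the irreproducible discovery rate (IDR), which compares the ranks of peaks between replicates. The list past the IDR threshold is called the IDR list here. The aligner, the peak caller, the IDR threshold and the read depth are not given in the sources used here, and the control was not analysed here. Each list was deposited on genome builds dm6 and dm3. Every peak carries a signal value as deposited by the authors, whose scale is not given in the sources used here, and a deposited −log10 q-value. The signal is the authors' own value per peak and was used to rank and describe peaks within a list. The −log10 q-values, deposited by the authors, were used only to describe the lists. The relaxed lists hold 30000 peaks each on both builds. The dm6 IDR list equals the 2704 peaks of highest signal in the dm6 relaxed list of both replicates, which is 9.01% of that list. It holds 2701 distinct intervals, since a few long peaks carry more than 1 summit.

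Coordinates are dm6 and 1-based. Genes and transcription start sites (TSSs) came from Ensembl release 115 and bases from the Release 6 genome. Annotated transposable elements were kept apart from genes. The dm3 lists were compared with each other by position and chromosome and were not annotated. A summit counted as promoter within 500 bp of any TSS, and other summits took the first class that applied among 5' UTR, coding, 3' UTR, noncoding exon, intron and intergenic. Positions downstream of genes were counted as intergenic. The background was the relaxed peaks of both replicates whose summits lie over 500 bp from every IDR summit. Replicates were compared as the share of replicate 2's 2704 highest peaks with a summit within 100 bp of one of replicate 3's 2704 highest, beside 1000 random draws from replicate 3's relaxed list.

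Shares were tested with a two-sided Fisher's exact test, with odds ratios given with 95% Woolf intervals and shares with 95% Wilson intervals. Where a cell was 0, a small constant was added to all cells of the odds ratio. Intervals cover counting error only. Peaks and genes are not biological replicates, so the p-values describe these lists and not the spread between embryo collections. A gene counted as bound when an IDR summit lay within 500 bp of a TSS, and it was tested when a relaxed summit did. Benjamini-Hochberg adjustment ran over the 18 gene lists with at least 5 tested members, over the 17 motifs and over the 2080 6-mers with reverse complements merged. The adjusted p threshold was 0.05. Sequence windows reached 100 bp to each side of the summit and were compared with background windows matched on promoter class and on GC content in steps of 5 percentage points, up to 5 per IDR window. Of 13520 windows wanted, 11680 were found. Mean GC content was 35.4% in IDR windows, 36.2% in matched and 38.6% in all background windows. Median signals were compared by a two-sided permutation test with 100000 resamples.

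The tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The 21 lists are cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, translation factors, proteasome subunits, oxidative phosphorylation, histone genes, tRNA genes, snRNA and snoRNA genes, DNA replication and cell cycle, architectural and promoter proteins, Polycomb and Trithorax group, Hox genes, segmentation genes, dorsoventral patterning, neural genes, muscle genes, cuticle genes, heat shock genes, ecdysone response genes, chorion and yolk genes, and chemoreceptor genes. One symbol, Z4, matched no gene of the annotation. The named genes are CG13123, the genes with the TSS nearest to the 20 loci of highest signal, up to 4 members per list with the highest IDR signal at a promoter, and up to 2 genes with the most IDR summits between their ends. The alternatives were other TSS windows, summit distances and list sizes, the 1352 IDR peaks of highest signal, other backgrounds, the dm3 lists, and each replicate's own 2704 highest peaks with the other replicate left out.

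The functions were tested on simulated data. With nothing planted, 0 of 2080 6-mers were called between random sets of background windows. Of 20 words planted in 5% of windows, 19 were called among 2080 6-mers, and of 20 planted in 10%, 20 were called. When bound genes were drawn at random from the 8330 tested genes, 3 of 100 draws called any of the 18 lists. When ribosomal protein genes were favoured 5 times, 100 of 100 draws called that list. Genes were drawn independently, so these draws leave out false calls from genes that share a promoter. Random splits of the background gave a promoter difference at the threshold in 5 of 100 draws. Shuffled signals passed in 0 of 20 draws and a rise of 20% at promoters in 20 of 20. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.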

Results

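The deposited peak lists describe where precipitation against GFP enriched DNA in whole embryos of 0 to 24 h. The embryos carried CG13123-GFP, a GFP-tagged protein of the fruit fly. No precipitation from flies without the tagged protein was analysed here. Enrichment that any GFP precipitation could give therefore stays open for all results below. The group comprised 2 biological replicates, numbered 2 and 3. The IDR list held 2704 peaks on dm6, which formed 2634 loci once overlapping peaks were joined, and 2739 peaks on dm3. The signal of the IDR peaks ran from 75.5 to 1992 with a median of 113, and the lowest −log10 q-value was 3.20. Median peak width was 400 bp. The lists carry no read counts, so the depth of the libraries is unknown.

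The replicates placed their strongest peaks at the same sites. Promoters of the ribosomal protein genes RpL34b and RpS21 and of CG30122 ranked 1, 3 and 2 in both replicates. Of the 2704 highest peaks of replicate 2, 1874 had a summit within 100 bp of one of replicate 3's 2704 highest, a share of 69.3% (Wilson interval 67.5 to 71.0%). Random draws from replicate 3's relaxed list gave a mean of 8.19% and at most 9.80% in 1000 draws. With summits required within 50 bp the share was 54.5%. Of the IDR peaks, 2586 (95.6%) had a relaxed peak in both replicates, and their signals correlated across peaks with Spearman's rho 0.691 and, on the log2 scale, Pearson's r 0.781. The IDR list equals the 2704 highest peaks of the relaxed list of both replicates, so this presence and these correlations are conditioned on that selection by joint signal. Peaks are not independent replicates, so no p-value is attached. No entry was identical between both replicates' lists.

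**Figure D1:**
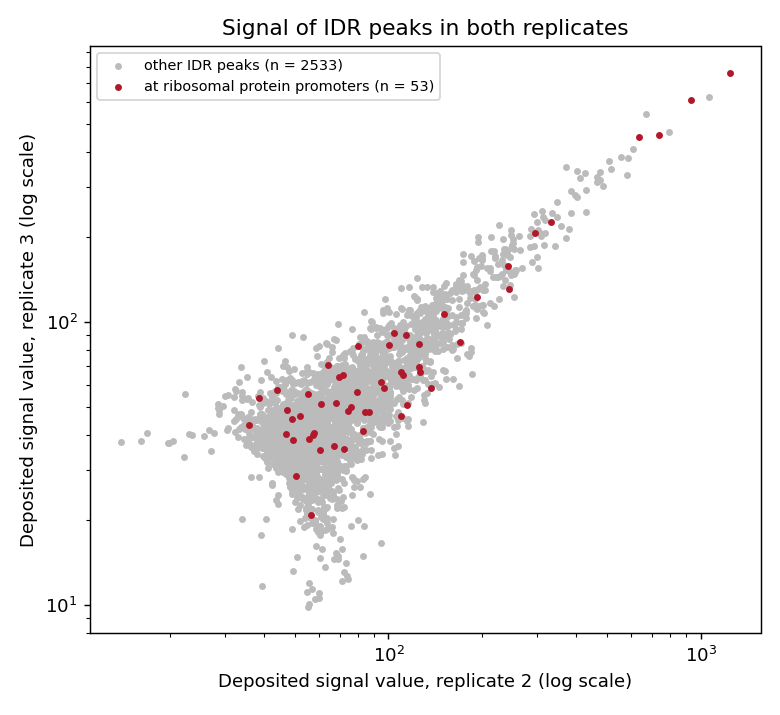
Deposited signal of each IDR peak in replicate 2 (horizontal, log scale) and replicate 3 (vertical, log scale); each point is 1 of the 2586 peaks found in both, and red points are the 53 within 500 bp of a cytoplasmic ribosomal protein TSS. RpL34b lies highest in both, at 1242 and 761.

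The strongest peaks included several promoters of genes of protein synthesis. RpL34b led with a signal of 1992 at 3R 9401077 to 9401587, with its summit 62 bp from the TSS. CG30122 followed with 1679 at 2R 18639022 to 18639539, 6 bp from the TSS, and RpS21 with 1548 at 2L 2855724 to 2856272, 11 bp away. Uhg4, a host gene of small nucleolar RNAs, had 1261 at 2R 9094959 to 9095384. CG14100 had 1208, RpS27 1188, RpL28 1087 and Ugalt 1012. RpL28 shares its peak with the translation factor gene eIF1, whose TSS lies 304 bp from the summit. Promoter peaks at px (signal 940), lncRNA:CR31840 (908), Ppcs (876), Art3 (813), Kap-alpha3 (792), Chro (775), CG1888 (759) and mRpL41 (743) also ranked among the 20 highest loci. The Art3 peak is shared with mRpS10, 133 bp from its TSS. The other 4 of these loci lay away from promoters. The summit assigned to cbt, 1398 bp from its TSS, lies in an intron of ush, and those at CG11050 and Lk6 lie in introns of those genes, 1030 and 984 bp from a TSS. The intergenic peak at 2R 13035173 to 13035515 had a signal of 797, and the nearest TSS, that of CG13323, was 11916 bp away.

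IDR peaks lay at promoters more often than weaker peaks. Of the 2704 IDR summits, 1520 (56.2%, interval 54.3 to 58.1%) lay within 500 bp of a TSS, against 7130 of 26731 background summits (26.7%). The odds ratio was 3.53 (3.26 to 3.83; Fisher's exact p = 1.03e-205, over peaks). The median distance to the nearest TSS was 319.5 bp for IDR and 1598 bp for background summits. Introns held 825 IDR summits (30.5% against 42.7% of background) and intergenic sequence 301 (11.1% against 17.9%). Coding sequence away from promoters held 6 (0.222% against 5.06%), 3' UTRs 13 (0.481% against 5.66%), 5' UTRs 18 and noncoding exons 21. Transposable elements held 4 IDR summits (0.148%) and 281 background summits (1.05%), an odds ratio of 0.139 (exact p = 7.46e-08). No IDR summit lay inside a tRNA gene, against 25 of the background, which was not past the threshold (exact p = 0.163).

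Promoter peaks were stronger than the rest of the IDR list. Median signal was 119 (quartiles 93.2 and 171.7) at the 1520 promoter peaks and 106 (87.9 and 144.8) at the other 1184, a difference of 12.6. The permutation p over peaks was 1e-05, the smallest that the resamples can give. Each replicate's own list gave smaller differences, of 3.34 for replicate 3 and 4.85 for replicate 2. Signals in those lists also run lower, and whether that accounts for the smaller differences was not tested.

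Among chromosome arms, chromosome 4 held few IDR peaks. It had 15 (0.555%) against 2.23% of the background, an odds ratio of 0.245 (0.147 to 0.410; Fisher's exact adjusted p = 1.37e-10 over 6 arms). By length the shortfall was smaller, at 11.1 IDR peaks per Mb against 19.0 to 22.4 on the other arms. The X chromosome had 447 IDR peaks, 16.5% against 16.0% (odds ratio 1.04, exact p = 0.441). In replicate 3's own list the odds ratio of the X was 1.12, with an unadjusted exact p of 0.0358. Arms 2L, 2R, 3L and 3R had 527, 489, 583 and 643 IDR peaks and did not pass. Within genes, lncRNA:CR44357 on the X (7166451 to 7405797) spanned 12 IDR summits. CG1677, which lies within the same interval, spanned 10. So did ush on 2L, which encodes a cofactor of GATA factors and tied for that place. These counts are not adjusted for gene length. Per 100 kb they were 5.01 for lncRNA:CR44357, 8.02 for CG1677 and 15.5 for ush, while CHES-1-like, with 7 summits, had 25.9.

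Genes for cytoplasmic ribosomal proteins were bound most often among the lists tested. A promoter peak of the IDR list was present at 2152 of the 8330 genes with any relaxed promoter peak (25.8%). For ribosomal protein genes it was 52 of 82 (63.4%, interval 52.6 to 73.0%; odds ratio 5.07, Benjamini-Hochberg adjusted exact p = 1.28e-11 over 18 lists). RpL34b, RpS21, RpS27 and RpL28 had the highest signals. tRNA genes were bound least among the lists past the threshold, at 9 of 169 (5.33%, odds ratio 0.158, adjusted exact p = 3.19e-11). Their highest signal, beside tRNA:Trp-CCA-2-2, was the peak at the CG30122 TSS, and tRNA:Tyr-GTA-1-8 had 331, tRNA:His-GTG-1-3 had 151 and tRNA:Phe-GAA-1-2 had 137. snRNA and snoRNA genes were bound at 14 of 125 (11.2%, odds ratio 0.358, adjusted exact p = 0.000451). Their strongest members shared host promoters, with snoRNA:Or-aca5 and snoRNA:Psi28S-2949 at the Uhg4 peak and snoRNA:Or-CD11a at the RpL28 peak, while snoRNA:Psi18S-1275 had 154. That last call ended when genes sharing a promoter were counted once (odds ratio 0.817, adjusted exact p = 0.735, chosen after seeing the data) and with a TSS window of 1000 bp (odds ratio 0.684, adjusted exact p = 0.145).

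No other list passed the threshold among genes with a relaxed promoter peak. Against all annotated genes, where genes with no relaxed peak enter, 11 lists passed in all. Mitochondrial ribosomal protein genes were bound at 24 of 59 (40.7%, odds ratio 1.98, adjusted exact p = 0.0595), led by mRpS10 with 813, mRpL41 with 743, mRpS23 with 613 and mRpL23 with 447. Counting shared promoters once moved that list past the threshold (odds ratio 2.43, adjusted exact p = 0.00639). Polycomb and Trithorax group genes were bound at 8 of 17 (adjusted exact p = 0.139), with ph-p at 714, brm at 320, E(z) at 244 and mor at 103. Architectural and promoter proteins stood at 7 of 16 (0.331), with Chro, Dref at 396, Cp190 at 331 and M1BP at 153. Heat shock genes stood at 6 of 14 (0.428), with Hsp27 at 308, Hsc70-5 at 185, Hsp83 at 166 and Hsp26 at 135. Translation factors stood at 12 of 34 (0.428), where eIF6 had 439, eIF4EHP 389 and eEF1gamma 222. DNA replication and cell cycle genes stood at 9 of 28 (0.669), with RnrS at 162, dpa at 144, Dp at 139 and aurA at 128. Oxidative phosphorylation genes stood at 16 of 56 (0.776), with COX5A at 165, ND-24 at 164, ND-ASHI at 162 and ND-MWFE at 151. Proteasome subunits stood at 7 of 30 (0.942), with Rpn5 at 142, Rpn3 at 141, Rpn6 at 132 and Rpn8 at 96.1. The values in parentheses for these lists are adjusted exact p-values, and the figures after gene symbols are peak signals.

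Lists of developmental and stage-specific genes gave small counts. Muscle genes were bound at 4 of 12 (adjusted exact p = 0.669), namely Msp300, tin, sls and Tm1. Tm1 had no relaxed peak within 100 bp in replicate 2. Ecdysone response genes were bound at 2 of 9 (adjusted exact p = 1), Eip75B with a signal of 199 and Hr78 with 86.4, and at 1 of 9 in replicate 2's own list. Segmentation genes stood at 1 of 10, with bcd at 108, dorsoventral patterning at 1 of 10, with rho at 83.7, and Hox genes at 1 of 5, with Dfd at 81.2; their adjusted exact p-values were 0.669, 0.669 and 1. In replicate 3's own list these 3 lists had 0 of 8, 0 of 9 and 0 of 7 bound, and in replicate 2's own list 2 of 11, 2 of 12 and 1 of 5. Cuticle genes had 0 of 15 bound, for which the Wilson interval reaches 20.4%, and chemoreceptor genes 0 of 13, reaching 22.8% (adjusted exact p = 0.0595 and 0.0823). Chemoreceptor genes passed in replicate 3's own list (odds ratio 0.0601, adjusted exact p = 0.00630). Fewer than 5 members could be tested for histone genes (1 of 4, His2Av at 168), neural genes (1 of 3, elav at 267) and chorion and yolk genes (0 of 3).

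**Figure D2:**
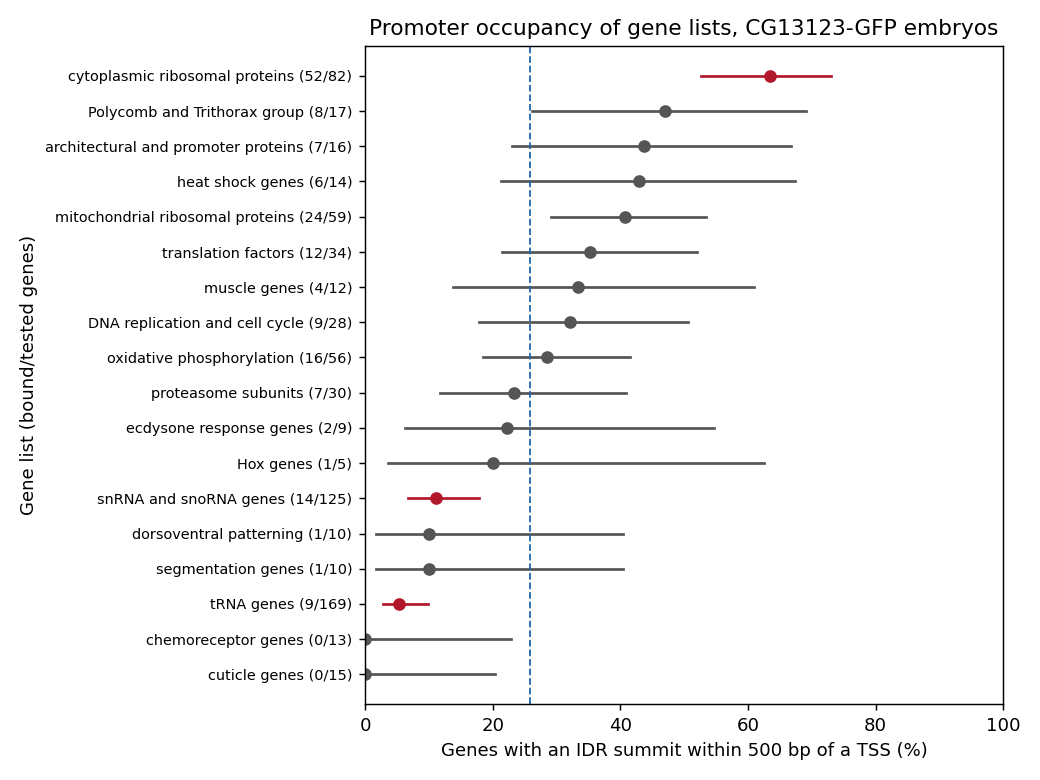
Share of tested genes with an IDR summit within 500 bp of a TSS (horizontal, percent), per gene list (vertical, bound and tested genes in parentheses); points are shares, bars 95% Wilson intervals, red marks an adjusted p below 0.05, and the dashed line is the share over all tested genes, 25.8%. Cytoplasmic ribosomal proteins lie above it at 63.4%, and tRNA genes below it at 5.33%.

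At summits, known promoter and insulator motifs were the most enriched of the fixed set. Motif 7, a core promoter element with consensus KNNCAKCNCTRNY, was in 7.06% of IDR windows and 3.53% of matched background windows (odds ratio 2.08, Benjamini-Hochberg adjusted exact p = 1.51e-13 over 17 motifs). The site of the insulator protein CTCF was in 2.33% against 0.942% (odds ratio 2.51, adjusted exact p = 3.36e-07). The DNA replication element, bound by DREF and BEAF-32, was in 4.77% against 2.95% (odds ratio 1.65, adjusted exact p = 2.74e-05). Its enrichment was absent among the 1352 IDR peaks of highest signal, where the odds ratio was 0.997. The TATA box (37.1% against 33.6%) was enriched, and the initiator (16.1% against 18.1%) and the TCT initiator (20.9% against 23.3%) were depleted, with odds ratios of 1.16, 0.868 and 0.872 and adjusted exact p-values of 0.00316, 0.0396 and 0.0278. These 3 calls ended among the 1352 IDR peaks of highest signal (odds ratios 1.07, 0.858 and 0.914) and with a background matched 1 to 1, the latter chosen after seeing the data. The TATA box also failed to pass in windows of 50 bp to each side, the initiator in windows of 50 or 200 bp and in replicate 3's own list (0.882), and the TCT initiator in windows of 200 bp and in either replicate's own list (0.968 and 0.995).

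The other 11 motifs did not pass in the windows of 100 bp with the matched background. Odds ratios were 0.992 for motif 1, bound by M1BP, 0.954 for motif 6, 1.18 for the E-box CAGCTG, 1.21 for the GAGA element and 0.887 for the Zelda site. They were 1.08 for the Su(Hw) site, 1.09 for the GATA site, 1.00 for the homeodomain site, 1.05 for the Grainyhead site, 0.746 for the Mef2 site and 0.970 for the Su(H) site. In replicate 3's own list the E-box, the GAGA element and the GATA site passed (odds ratios 1.29, 1.53 and 1.11), and in replicate 2's own list the E-box did (1.22). In windows of 200 bp to each side the GAGA element, the E-box and motif 1 passed (1.64, 1.39 and 1.45), and against the unmatched background motif 1, the GATA site and the homeodomain site did (1.71, 1.17 and 1.18).

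**Figure D3:**
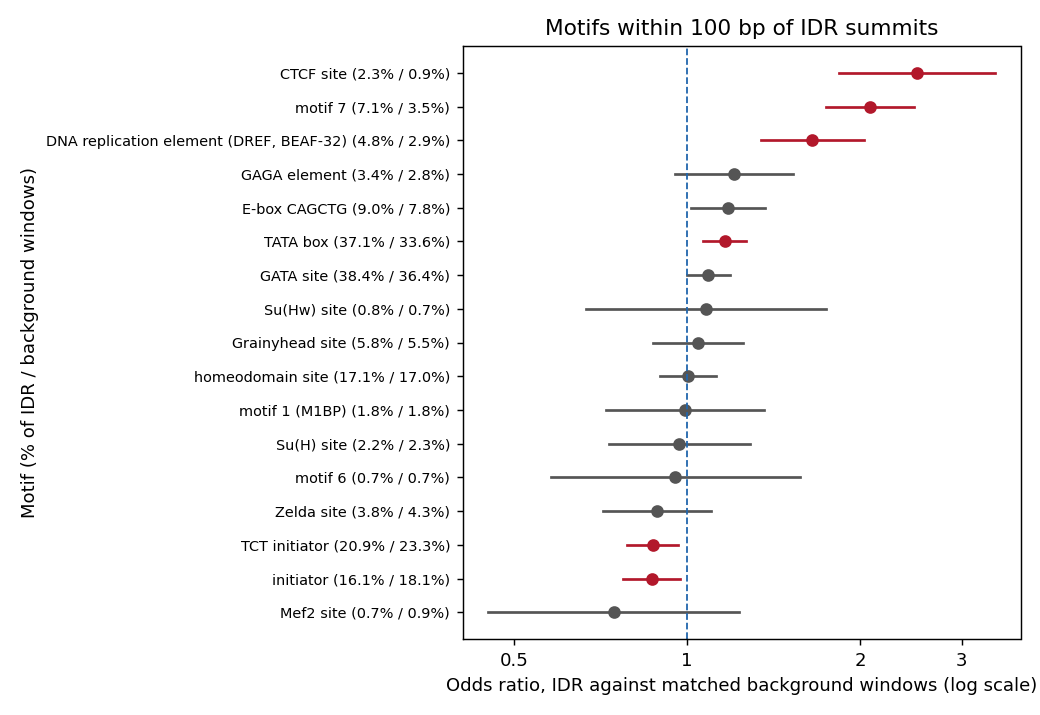
Odds ratio of each motif (horizontal, log scale) in windows of 100 bp to each side of IDR summits against matched background windows, with the share of IDR and background windows in parentheses; points are odds ratios, bars 95% Woolf intervals, and red marks an adjusted p below 0.05. Motif 7 lies at 2.08 and the CTCF site at 2.51.

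Without assuming a motif, 171 of 2080 6-mers were enriched at IDR summits and 174 depleted. The 10 named words are those of highest odds ratio among enriched 6-mers in at least 5% of IDR windows. ACAGTG led them, in 19.8% of IDR and 10.5% of background windows (odds ratio 2.10, interval 1.88 to 2.35, Benjamini-Hochberg adjusted exact p = 4.89e-33). ACACTG was in 19.7% against 11.5% (odds ratio 1.89), and ACTGTA in 14.7% against 9.00% (1.74). The other named words, ACAGGG, CTGTGC, GTGCAC, ACTGTG, CAGTGC, GTACAC and CAGTGG, had odds ratios from 1.64 to 1.73. ACAGTG, CAGTGC, CAGTGG and the reverse complement of ACACTG share the bases CAGTG, so these words are not independent. ACAGTG and CAGTGC can also be part of a match of the core promoter element KNNCAKCNCTRNY, read on its other strand. The enrichment of that element and of these words may therefore not be separate findings. How often their matches coincide was not tested. The number enriched was 62 with a background matched 1 to 1 and 364 without matching.

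The tagged gene's own locus carried no strong peak. CG13123 lies on the minus strand of 2L from 9791961 to 9793107, and the nearest IDR summit was 29807 bp from its TSS. A relaxed peak of both replicates had its summit 130 bp from the TSS, with a signal of 20.4 and rank 27441 of 30000. Within 50 kb of the gene there were 2 IDR summits, where the other 2656 protein-coding genes of the arm had a median of 3. In replicate 2 the nearest relaxed summit was 129 bp from the TSS and in replicate 3 it was 795 bp away.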

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

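Some relaxed peaks lay on the dm3 heterochromatic and unplaced sequences. The dm3 share of the X left these sequences out, while the dm3 replicate overlap set no limit on sequences. No comparison examined them on their own. The relaxed dm3 lists had 77 peaks there for both replicates together, 61 for replicate 2 and 188 for replicate 3. These were 0.257%, 0.203% and 0.627% of the lists, and each count was above the limit of 3 set for flagging. The relaxed lists hold background as well as peaks, so these counts cannot tell signal from background. The dm3 IDR list had 0 of 2739 there. No explanation was tested.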

How the results depend on the processing

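The alternatives with a background matched 1 to 1 and with shared promoters counted once were chosen after seeing the data. The number of IDR peaks, the promoter enrichment and the signal difference kept their direction and side under every alternative run for them, with promoter odds ratios from 2.93 to 8.27. The 10 named 6-mers did so in 67 of 70 values, the gene lists in 101 of 124 and the motifs in 80 of 119. For the values below, the cause was not tested. Replicate overlap was 54.5% with summits within 50 bp, 74.5% within 200 bp, 74.3% for the 1352 and 59.5% for the 5408 highest peaks. The X odds ratio was 0.968 for the 1352 strongest IDR peaks, 0.928 against arm lengths, and 1.01 to 1.12 with a replicate left out.

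The 1352 strongest IDR peaks gave 2 motifs and 69 enriched 6-mers past the threshold, 61.2% promoter summits, 1 summit at the tagged locus, and odds ratios of 0.827 for oxidative phosphorylation, 0.966 for DNA replication and cell cycle, 0.997 for the DNA replication element and 0.985 for the homeodomain site. Within 20 kb of CG13123 there were 0 IDR summits. With a TSS window of 200 bp, odds ratios were 1.12 for proteasome subunits and 0.169 for muscle genes, and that of tRNA genes moved from 0.158 to 0.0621. With 1000 bp they were 0.684 for snRNA and snoRNA genes, 1.15 for dorsoventral patterning and 0.115 for cuticle genes. Against all annotated genes, where genes with no relaxed peak enter, 11 lists passed and cytoplasmic ribosomal proteins moved from 5.07 to 9.65. The odds ratios that changed side or direction were 3.67 for mitochondrial ribosomal proteins, 2.30 for translation factors, 1.27 for proteasome subunits, 2.92 for DNA replication and cell cycle, 5.22 for architectural and promoter proteins, 4.26 for Polycomb and Trithorax group, 1.06 for Hox genes, 0.0350 for cuticle genes, 1.35 for ecdysone response genes and 0.0205 for chemoreceptor genes. With shared promoters counted once they were 2.43 for mitochondrial ribosomal proteins and 0.817 for snRNA and snoRNA genes, and tRNA genes had 0.255.

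For motifs, windows of 50 bp each side gave 72 enriched 6-mers and odds ratios of 0.900 for the GAGA element, 1.07 for Zelda, 0.991 for Su(Hw) and 1.14 for Su(H). With 200 bp, where the GAGA element (1.64), the E-box (1.39) and motif 1 also passed, they were 1.45 for motif 1, 1.15 for motif 6, 0.959 for Su(Hw), 0.989 for the homeodomain site and 1.02 for Su(H). An unmatched background gave 364 enriched 6-mers, 1.71 for motif 1 and 1.64 for motif 6, and motif 1, the GATA site (1.17) and the homeodomain site (1.18) passed. Matching 1 to 1, which leaves fewer background windows, gave 3 motifs, 62 enriched 6-mers, 1.06 for motif 6 and 0.950 for the homeodomain site.

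With a replicate left out, odds ratios ranged from 0.692 to 1.28 for proteasome subunits, 0.917 to 1.29 for oxidative phosphorylation, 0.962 to 2.26 for muscle genes, 0.360 to 0.775 for ecdysone response genes, 0.159 to 0.641 for segmentation genes, 0.143 to 0.577 for dorsoventral patterning, 0.181 to 0.721 for Hox genes, 1.73 to 3.11 for architectural and promoter proteins, 2.11 to 3.62 for Polycomb and Trithorax group, 0.0601 to 0.0928 for chemoreceptor genes, 1.06 to 1.34 for motif 1 and 0.949 to 1.38 for motif 6. Promoter summits ranged from 57.2 to 58.1%, and 1 to 2 summits lay at the tagged locus. The depth of the libraries is unknown, so its effect on these values was not assessed. No paired analysis was possible because there is only 1 group. Replicate overlap needs both replicates and the number of IDR peaks is the authors' joint list, so neither was recomputed without a replicate.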

Other observations

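All tests in this part were chosen after the result they bear on had been seen. A 7-base word marked some of the strongest peaks. CGCAGCC, which reads GGCTGCG on the other strand, had the lowest p among 7-base words in the 100 strongest windows. It was in 13 of them (13.0%, Wilson interval 7.8 to 21%) against 160 of 11680 background windows (1.37%), which were matched to the whole IDR list. In 11 of the 13 it was part of the 12-base form CGCAGCCAACTT. The TSSs nearest to those windows are of RpS21, RpS27, RpL28, RpL27A, RpS28b, CG30122, Ppcs, Kap-alpha3, trc, CG31886 and Fdh. At RpS21 the word lies on 2L at 2856083 to 2856089, and at RpL34b, where the form reads CGCAGCCAAGTT, on 3R at 9401255 to 9401261. The 12-base form occurs 48 times on the major arms, and 13 of these lie within 100 bp of an IDR summit, of which 11 are in the windows it was read from and 2 below rank 100. Of the 14905 matches of CGCAGCC itself, 42 (0.282%) lie within 100 bp of an IDR summit. Once windows with CGCAGCC were set aside, CTACGCC had the lowest p in the rest of the 100 strongest. It was in 10 of the 100 strongest windows and in 6 of the following 100, against 0.736% of background windows. CGCAGCC was in 0 of those following 100. Below rank 100, where neither word was selected, CTACGCC kept an odds ratio of 1.84 (1.24 to 2.73) and CGCAGCC had 0.811 (0.545 to 1.21).

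As to the word CGCAGCC, copies of one repeated sequence are argued against: none of the 13 summits lies in an annotated transposable element, and the 30 bases on each side were alike in 33.7% of positions on average. The choice was repeated on 1000 random draws of 100 IDR windows, and 3 draws gave a word with as low a p (permutation p = 0.00400). This argues against a chance choice among many words in windows drawn from the whole IDR list. Neither the draws nor the background were matched to the 100 strongest windows on promoter class and GC content, so a difference in these stays open. A general mark of the IDR peaks is argued against too, with an odds ratio of 0.811 (0.545 to 1.21) below rank 100. The word may mark a small class of strong sites, a hypothesis from the same data that found it. No biological explanation was tested.

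Cytoplasmic ribosomal protein genes were bound at 52 of 82, and translation factor, proteasome and oxidative phosphorylation genes together at 35 of 120 (29.2%), an odds ratio of 4.21 (2.32 to 7.65; Fisher's exact p = 1.62e-06), which argues against the promoters of these lists being bound alike. Mitochondrial ribosomal protein genes, left out of that pool, stood at 24 of 59 (odds ratio 2.53, 1.27 to 5.02; exact p = 0.0101). Cytoplasmic ribosomal protein genes were singled out as the highest list in these same counts, so neither test is independent support. The word CGCAGCC was in 8 of 54 ribosomal protein promoter peaks, but 6 of the 8 are among the windows in which the word was selected. Among those 100 strongest windows it was in 6 of 7 ribosomal protein promoter peaks and 6 of 63 other promoter peaks. No test is given for these counts, because the word was selected there. Below rank 100 the word was in 2 of 47 ribosomal protein promoter peaks (4.26%, Wilson interval 1.17 to 14.2%). This argues against the exact word drawing most of those peaks, and its part among the strongest peaks stays open. Enrichment that any GFP precipitation could give at these promoters also stays open, because no precipitation from flies without the tagged protein was analysed here.

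The odds ratio of ACAGTG, 2.10, exceeded those of the 179 other 6-mers made of the same bases, whose highest was 1.56. ACAGTG was selected for its high odds ratio, so this rank was largely fixed by the choice. The median of the others was 0.944, which argues against base composition alone raising such words. ACAGTG did not gather at the summit: 119 matches lay within 25 bp and 168 beyond 75 bp, against 308 and 347 in the background (odds ratio 0.798, Fisher's exact p = 0.118). Matches per 100 IDR windows ran from 1.59 to 1.85 in steps of 10 bp up to 30 bp and from 2.59 to 3.25 between 50 and 80 bp, against 0.925 to 1.31 in any step of the background. The spread over the 10 steps was short of the threshold for a difference from the background (permutation p = 0.0538), so a broad sequence of the bound regions stays open, and no biological explanation was tested. The longer word ACAGTGG had the lowest p in the 100 strongest windows once those with CGCAGCC or CTACGCC were set aside. Its share of 15% there may therefore be raised by that choice. Outside them it was in 13% of windows at ranks 101 to 200, 14% at 201 to 400 and 8.5% at 401 to 800. It was in 8% at ranks 801 to 1600 and 7.52% at 1601 to 2704, against 3.46% of background windows.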
